A study of Mus musculus with 12 samples.

How the data were processed

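Liver RNA of mice was profiled by RNA-seq in 12 libraries, 4 in each of 3 groups, per the labels. The first group is young control liver. The titles of the second group call it an aged control while its description names doxo, an abbreviation read here as doxorubicin, a DNA-damaging chemotherapy drug. It is called aged/doxo below because the labels do not settle which treatment or age it stands for. The third group was treated with the compound coded KSL0608-Se, and its description names doxo as well. The labels call the libraries of a group replicates and the design text calls them a quadruplicate. Nothing says how animals map to libraries, so p-values measure the spread between these libraries.

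The deposited values are TPM (transcript abundances scaled to a fixed total per library) made by the authors for 55903 genes, rounded to 2 decimals. Each library summed to about 1000000 TPM. Reads were processed with fastp, a read trimmer, HISAT, a spliced aligner, and RSEM, an expression estimator, per the submitters' processing notes, which name no versions or order. The genome build and annotation release are not given in the sources used here. Of the gene identifiers, 55487 were Ensembl identifiers, of which 55141 were found in GENCODE M21, and 416 were assembled loci without a symbol. TPM keeps no sequencing depth, so the depth behind each value is unknown and no counting interval was computed. TPM also sums to a constant, so a few abundant genes can shift all others. Strandedness is not given in the sources used here, so genes that overlap on opposite strands, and near-identical copies such as the Mup genes, were read as uncertain. No library held the same values as another. Positions are those of GENCODE M21 on GRCm38, matched by gene identifier.

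Values were analysed as log2(TPM + 1), with a pseudocount of 1, in the 10883 genes with a mean TPM of at least 1 over all libraries. Fold changes on this scale understate the change of low genes. limma 3.58.1 in R 4.3.3 fitted a linear model with group as the only term to all 12 libraries together, with an intensity trend in the variance. All tests were two-sided and were adjusted by Benjamini-Hochberg, with 0.05 as the threshold. Intervals are 95% intervals from the same model. Before the data were examined, 37 gene lists for liver cell types and pathways and a panel of 24 senescence genes were fixed. The 35 lists with at least 5 measured members were tested with camera at its preset correlation of 0.01. Members were also counted after adjustment over the list alone. That adjustment makes no allowance for the number of lists or comparisons, so such passes are weaker than calls over all genes. Each list was tested again with camera at an estimated correlation, with fry, and, chosen after seeing the data, by an exact permutation test of the mean log2(TPM + 1) of the list per library. Panel genes were tested by a two-sided exact permutation test over all 70 divisions of 8 libraries into 4 and 4, for which the smallest p is 0.0286. After adjustment over many genes or lists, a few values at this smallest p cannot pass.

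Named genes followed a rule fixed before the data were examined. It took genes with an established symbol, an adjusted p under 0.05 and no overlap between groups, the 10 largest changes in each direction. Where fewer than 3 passed in a direction, the 5 of smallest p were named as not passing. Up to 4 members of smallest p were named from each list described, and panel genes could be named throughout. Other genes are said to have been chosen after their values were seen. The procedure was tested on simulated data for aged/doxo against young control over 10883 genes and 50 draws, each with 200 changed genes. It recovered 29.2% of genes changed 2-fold and 85.3% of genes changed 4-fold, with the change added on the log2(TPM + 1) scale. The same fold in TPM moves low genes less on this scale, so their recovery would be lower. Of 50 draws with no change, 4 gave any call. On such unchanged data the preset camera called 11.7 of the 35 lists on average, and 0.02 with an estimated correlation. Counts of list calls at the preset correlation were therefore read as no more than a ranking. With all p53 target genes raised by 1 on the log2 scale, the estimated correlation called that list in 37 of 50 draws. Smaller shifts were not simulated and may be missed.

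Alternatives covered the pseudocount (0.1 and 0.01), the filter (none, or a mean TPM of at least 5), median-of-ratios and quantile scaling, a total without the 50 most abundant genes and the mitochondrial genes, the replicate number as a block, robust and weighted fits, fits of the compared groups alone, a 2-fold minimum change, and leaving out each library. Chosen after seeing the data were a fit without young control library 1 and aged/doxo library 2, and a fit with each library's dependence on gene length as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.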

Results

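RNA-seq of mouse liver compared young control mice, an aged/doxo group and a group treated with the coded compound KSL0608-Se, with 4 libraries in each. The labels of the aged/doxo group name both age and doxo, and those of the treated group name doxo and the compound. The series title places the work in light-activated removal of senescent cells. The question addressed is therefore how liver transcripts differ between young control and aged/doxo mice, and whether KSL0608-Se treatment moves them back. The libraries held between 9568 and 11023 genes at 1 TPM or more, and their sequencing depth is unknown. All libraries were alike in sex-linked transcripts, with Xist at no more than 0.01 TPM and Ddx3y between 4.69 and 8.67 TPM.

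Libraries differed in ways that the groups did not account for. The first principal component held 54.9% of the variance in log2(TPM + 1), and 2 libraries lay apart on it, young control library 1 and aged/doxo library 2. It followed the slope of expression on gene length in each library (Pearson r = 0.906, permutation p = 1e-05; Spearman rho = 0.972, permutation p = 1e-05; n = 12 libraries). These p-values are the smallest that 100000 resamples can give. Slope and component are both weighted sums of the same values, so a strong relation is partly built in. It does not single out gene length among properties of genes. Without the 2 libraries of most extreme slope, r was 0.973. The labels give no batch within which to repeat this relation. Transcripts of the mitochondrial genome made up 27.6% of TPM in aged/doxo library 2 and between 9.82% and 11.5% in the other libraries of its group. The nuclear noncoding RNA Neat1 was chosen after its values were seen and stood at 88.0 TPM in that library and at 10.9, 34.9 and 17.9 TPM in the others of its group.

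**Figure D1:**
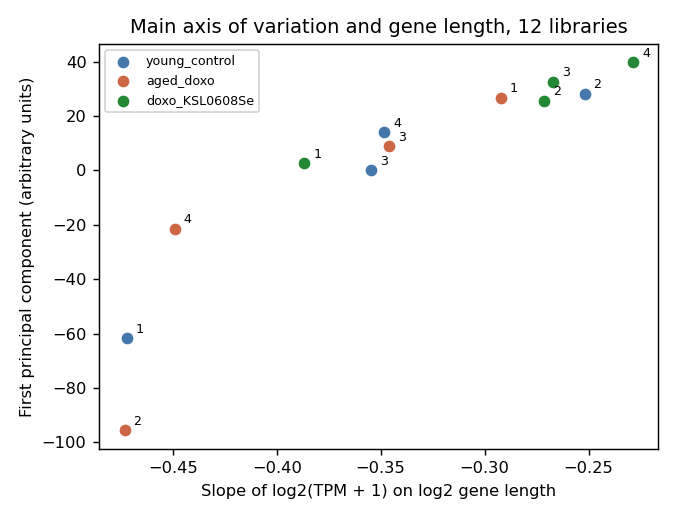
First principal component of log2(TPM + 1) (y axis, arbitrary units) against the slope of log2(TPM + 1) on log2 gene length (x axis) for 12 libraries, coloured by group and numbered by replicate. Libraries with steeper negative slopes lie lower, and young control library 1 and aged/doxo library 2, with slopes of -0.47 and -0.47, lie lowest (Pearson r = 0.906 by permutation test, n = 12).

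The first comparison asks how aged/doxo liver differed from young control liver. Of 18 measured genes activated by the tumour suppressor p53, 4 were higher in aged/doxo liver when adjusted over the list alone, none was lower and 14 did not pass. The list as a whole did not pass (estimated-correlation p = 0.00981, adjusted p = 0.172), and 4 of the 18 log2 fold changes were negative. The 4 higher genes were Phlda3, a p53-induced inhibitor of Akt signalling (4.74 ± 1.28 against 0.56 ± 0.23 TPM, SD, n = 4), the cell-cycle inhibitor Cdkn1a, which encodes p21 (22.8 ± 8.04 against 4.98 ± 3.05 TPM), the exonuclease gene Aen (11.1 ± 2.24 against 5.69 ± 0.865 TPM) and the pro-apoptotic gene Bax (44.3 ± 8.23 against 26.7 ± 4.32 TPM). Log2 fold changes on the log2(TPM + 1) scale were 1.86 ± 0.29 (SE) for Phlda3, 2.07 ± 0.37 for Cdkn1a, 0.84 ± 0.19 for Aen and 0.70 ± 0.21 for Bax. Their limma adjusted p over the list alone ranged from 0.00049 for Phlda3 to 0.0256 for Bax. Adjusted over all genes they did not pass, and Phlda3 had the smallest value of these (limma adjusted p = 0.148). Between 3 and 6 members of the p53 list passed without each library.

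Cdkn1a lies on chromosome 17 from 29090976 to 29100727 and Phlda3 on chromosome 1 from 135766119 to 135769136, both on GRCm38. Aen lies on chromosome 7 from 78895854 to 78911209, and Bax on the same chromosome from 45461697 to 45466898. All 4 are annotated as protein-coding genes.

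**Figure D2:**
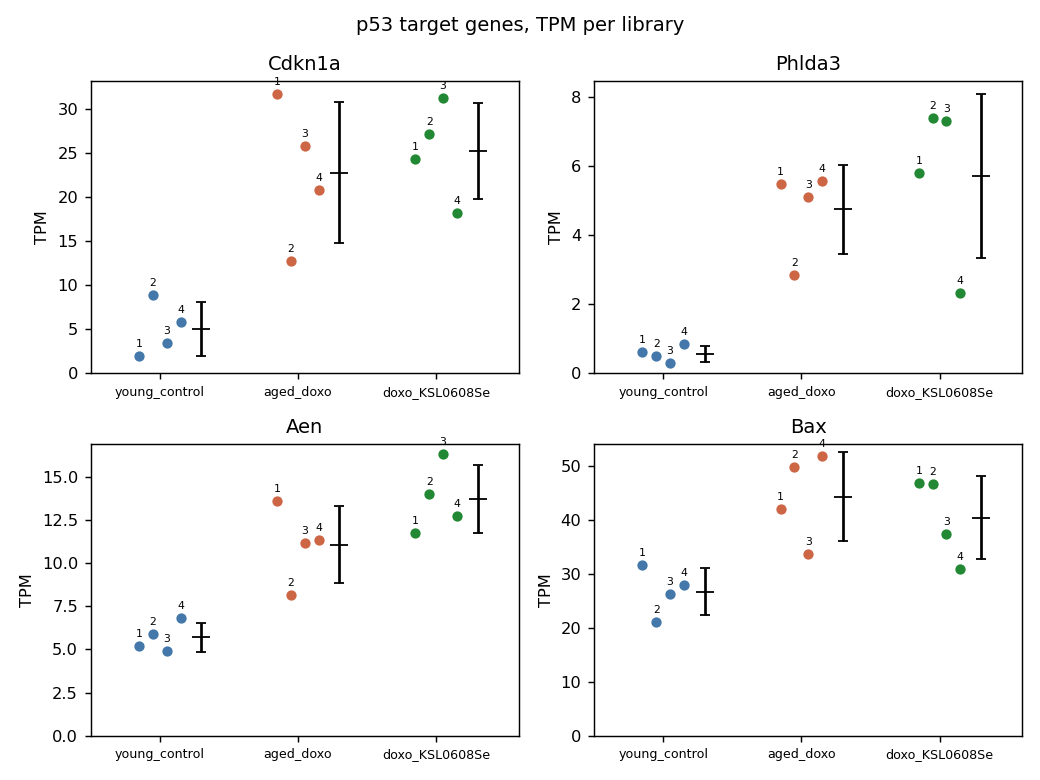
TPM (y axes) of the p53 target genes Cdkn1a, Phlda3, Aen and Bax in each library (points, numbered by replicate) of the 3 groups, with the group mean and SD (bars, n = 4). Young control libraries lie below all aged/doxo libraries for each gene, such as 1.89 to 8.89 TPM for Cdkn1a against 12.8 to 31.7 TPM.

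Over all 10883 genes, limma called 1 gene, which rose in aged/doxo liver, and 215 genes had an unadjusted p under 0.05 where 544 are expected by chance alone. The called gene was Gm45941, a long intergenic noncoding RNA on chromosome 12 from 27946042 to 27982234 that is outside the rule for named genes and was chosen after its values were seen. It stood at 7.54 ± 3.42 TPM in aged/doxo liver and 0.352 ± 0.207 TPM in young control liver (log2 fold change 2.59, SE 0.32, limma adjusted p = 0.0227, n = 4). Its call was lost without young control library 1, 2 or 3, without aged/doxo library 1, 3 or 4, or without treated library 1. Among genes not passing, Snhg15, a small nucleolar RNA host gene, had a log2 fold change of 0.84 ± 0.21. Snurf, which shares its locus with the imprinted gene Snrpn and so cannot be separated from it, was listed at 0 in all 4 aged/doxo libraries and in young control library 1, and at 4.45, 9.44 and 7.43 TPM in the others.

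Several major urinary protein (Mup) genes, male-enriched products of hepatocytes, were lower in aged/doxo liver. Of 30 measured male-biased liver genes, 7 fell, none rose and 23 did not pass when adjusted over the list alone. They included Mup1 (2958 ± 495 against 6365 ± 2515 TPM, log2 fold change -1.04), Mup7 (log2 fold change -1.10), Mup12 (log2 fold change -1.03) and the carboxylesterase gene Ces4a (log2 fold change -0.81), each at a limma adjusted p of 0.0273 over the list alone. The list's estimated-correlation p was 0.00839 (adjusted p = 0.172). Mup14, which is in no list, did not pass (log2 fold change -0.83). Mup copies are nearly identical, so single members are uncertain. All Mup genes together held 11.97% ± 2.20 of TPM in aged/doxo and 19.5% ± 5.24 in young control liver (SD, n = 4, exact permutation p = 0.0286, 0.257 adjusted over 9 tests of library measures). That p is the smallest this test can give, and alone it could not pass over 9 tests. No member of the list passed without young control library 1 or 3 or without aged/doxo library 2 or 4, with no filter or with the compared groups alone, and 1 passed with median-of-ratios scaling.

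**Figure D3:**
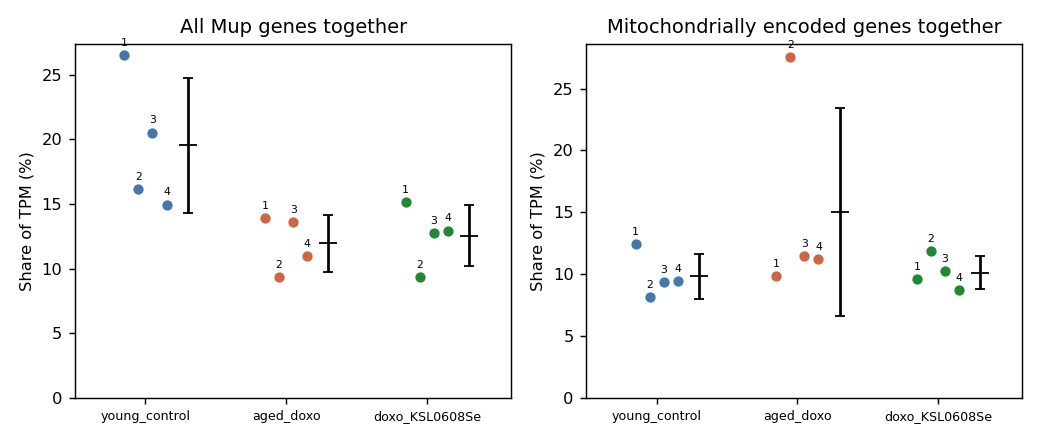
Share of TPM in percent (y axes) of all Mup genes together (left) and of mitochondrially encoded genes together (right) in each library (points, numbered by replicate), with group mean and SD (bars, n = 4). Mup shares were 9.32% to 13.9% in aged/doxo libraries and 15.0% to 26.5% in young control libraries, and the mitochondrial share of aged/doxo library 2 was 27.6%.

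Among 29 measured targets of the oxidative-stress regulator NRF2, the glutathione S-transferase genes Gsta1 and Gstm3 rose and 27 did not pass when adjusted over the list alone. Adjusted over all genes, neither Gsta1 nor Gstm3 passed. The list's estimated-correlation p was 0.0991 (adjusted p = 0.519). Gsta1 stood at 11.1 ± 1.65 against 3.59 ± 1.66 TPM (log2 fold change 1.48, SE 0.31) and Gstm3 at 83.0 ± 24.9 against 41.0 ± 9.32 TPM (log2 fold change 0.98, SE 0.25). Gstm1 and Aox1 did not pass, with log2 fold changes of 0.75 and 0.62. Without aged/doxo library 2, 6 members passed, and 1 passed without young control library 1 or 3 or aged/doxo library 1 or 3, with the replicate number as a block or with the compared groups alone. None of the 9 erythroid genes passed adjusted over the list alone, although the haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt had log2 fold changes of 0.87, 0.82, 0.84 and 0.80. None of the 24 fibrosis and stellate cell genes passed, with log2 fold changes of 1.09 for Acta2, 0.75 for Tagln, 0.58 for Vim and 0.52 for Col1a1. Macrophage and Kupffer cell markers had a median log2 fold change of -0.43 over 20 genes and none passed (estimated-correlation p = 0.325, adjusted p = 0.853). Their median was -0.11 without aged/doxo library 2, -0.24 without library 3, -0.25 without young control library 2 and -0.78 without aged/doxo library 4, where 7 passed. Without young control library 4, 4 erythroid and 2 fibrosis and stellate cell genes passed.

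At camera's preset correlation 11 lists were higher and 4 lower in aged/doxo liver, of 35. With an estimated correlation or fry, 0 lists passed, and 3 and 2 had an unadjusted p under 0.05. The erythroid list had an estimated-correlation p of 0.0248 (adjusted p = 0.289). Of the 24 panel genes, 0 passed, but a few genes at the smallest exact permutation p cannot pass adjustment over the panel. This count therefore says little about absence of change. By limma, Cdkn1a had an unadjusted p of 8.45e-05 and an adjusted p of 0.307 over all genes. Cdkn1a and the stress cytokine gene Gdf15 (7.77 against 4.74 TPM) reached the smallest exact permutation p of 0.0286, or 0.343 after adjustment over the panel. The senescence marker Cdkn2a, which encodes p16, averaged 0.065 TPM in aged/doxo and 0.102 TPM in young control liver, and 9 panel genes averaged under 1 TPM.

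The second comparison asks how KSL0608-Se treated liver differed from aged/doxo liver. No p53 target gene was called after treatment: 0 of 18 passed adjusted over the list alone in either direction. Cdkn1a stood at 25.3 ± 5.50 TPM in treated and 22.8 ± 8.04 TPM in aged/doxo liver (log2 difference 0.19, 95% interval -0.60 to 0.98, limma adjusted p = 0.744, n = 4), and this difference was negative under 7 alternatives. The interval excludes a fall as large as the difference of 2.07 between aged/doxo and young control liver. The 4 members of smallest p were Sesn2, Plk2, Trp53inp1 and Perp, with log2 fold changes of 0.44, 0.50, 0.53 and 0.55, of which Sesn2 alone had an unadjusted limma p under 0.05 (0.0440). The median of the list, 0.30, was that of all tested genes, 0.30. Changes against aged/doxo liver are given beside this 0.30, which holds for the deposited scale with all libraries. The median of all genes was 0.13 without aged/doxo library 2, 0.02 with the length slope as a covariate and 0.03 after quantile normalization, and -0.08 in the first comparison.

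Over all genes, limma called 1 gene, which fell in treated liver, and 519 genes had an unadjusted p under 0.05 where 544 are expected. This was Gm47551, annotated as antisense to Fcho2, on chromosome 13 from 98801172 to 98803736. It is outside the rule for named genes and was chosen after its values were seen. It was listed at 0 in 3 treated libraries and at 1.47 TPM in the other, and at 14.5, 58.1, 22.6 and 57.3 TPM in aged/doxo libraries (log2 fold change -4.74, SE 0.55, limma adjusted p = 0.0127). Without strand information its reads cannot be told apart from those of Fcho2, and its recorded length was only 165 bases. The call was lost without aged/doxo library 2 or 4, without treated library 1, 2 or 3, and under both added alternatives.

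Of 21 measured gluconeogenesis and fasting-response genes, G6pc, the glucose-6-phosphatase gene that completes glucose production, was higher in treated liver and 20 did not pass when adjusted over the list alone. G6pc stood at 160.2 ± 43.3 TPM in treated and 57.0 ± 25.03 TPM in aged/doxo liver (log2 fold change 1.58, SE 0.41, limma adjusted p = 0.044 over the list alone and 0.427 over all genes). It did not pass over the 26 periportal genes, a list that also holds it (adjusted p = 0.0545). The G6pc call was lost with the length slope as a covariate, the replicate number as a block, no filter or the compared groups alone, and without young control library 2, aged/doxo library 2, 3 or 4, or treated library 2, 3 or 4. Pck1, which acts earlier in the pathway, stood at 357 ± 104 against 151.6 ± 59.5 TPM (log2 fold change 1.31) and did not pass over this list (adjusted p = 0.0784). It passed over the 6 adipocyte genes, a list that also holds it (adjusted p = 0.0448). That call was kept only without young control library 3 or 4, aged/doxo library 4 or treated library 1, of the fits without each library. Tat and Creb3l3 had log2 fold changes of 0.99 and 0.89 and did not pass, with lowest values under the alternatives of 0.36 and 0.13. The median of the list was 0.55, and 0.25 without aged/doxo library 2. The list's estimated-correlation p was 0.403 (adjusted p = 0.917).

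Lipogenesis genes had a median log2 fold change of 0.71 over 28 genes, 0.41 above that of all genes, and none passed adjusted over the list alone. The desaturase gene Scd1 had a log2 fold change of 1.24, the elongase gene Elovl5 0.72, Acaca 0.92 and Mogat1 0.78. Their lowest values under the alternatives were 0.46, 0.30, 0.20 and 0.61, and the median of the list was 0.13 with the length slope as a covariate. The list's estimated-correlation p was 0.431 (adjusted p = 0.917), and its mean per library was higher in treated liver at the smallest exact permutation p of 0.0286 (0.444 adjusted over 35 lists). Cholesterol biosynthesis genes and PPARA and fatty acid oxidation genes had medians of 0.58 and 0.62, with estimated-correlation p-values of 0.429 and 0.466 (adjusted p = 0.917 for each). Without aged/doxo library 2 these medians were 0.25 and 0.27. None of the 28 endothelial markers passed, with log2 fold changes of 0.68 for Ptprb, 0.80 for Oit3, 0.61 for Flt4 and -0.83 for Stab1. Across the 35 lists, the mean log2 fold change followed the median gene length of the list (Spearman rho = 0.616 across lists, which share libraries and are not independent replicates).

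Among genes not passing, the smallest p belonged to Cd300ld3, Adgrv1, Tmem161a, G6pc and Gpx6 on the higher side, with log2 fold changes of 1.22, 0.89, 0.97, 1.58 and 0.85. On the lower side were Nexn, Mgp, Snhg9, Fxyd3 and Tnnt2, with log2 fold changes of -2.67, -1.42, -2.23, -1.31 and -1.36. Nexn and Tnnt2 encode muscle filament proteins and Mgp encodes matrix Gla protein, an inhibitor of calcification. The smooth muscle genes Acta2 and Tagln had log2 fold changes of -1.32 and -0.81, Col1a1 one of -0.44 and Reln one of 0.83, and none of the 24 fibrosis and stellate cell genes passed. The haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt had log2 fold changes of -0.96, -0.67, -0.76 and -0.73, and none of the 9 erythroid genes passed.

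At camera's preset correlation 6 lists were higher and 12 lower, of 35, and 0 passed with an estimated correlation or fry, where 2 and 1 had an unadjusted p under 0.05. The median of 8 of the 18 lists, and the mean of 7, had the opposite sign to the test, which compares a list with all other genes. Without aged/doxo library 4, 11 lists were called, and 8 of them were among the 18 in the same direction. Of the panel, 0 genes passed the exact permutation test and 0 had an unadjusted p under 0.05, with a smallest adjusted p of 0.549. Glb1, the lysosomal beta-galactosidase gene, stood at 6.85 against 5.26 TPM (exact permutation p = 0.0571, n = 4). Cxcl1 stood at 2.89 against 5.01 TPM (exact permutation p = 0.0857, n = 4).

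Genes that changed in aged/doxo liver and changed the opposite way with treatment were counted next. There were 0 such genes by limma at the adjusted threshold, and 50 at an unadjusted p under 0.05 in both comparisons. Both comparisons share the aged/doxo libraries, so opposite signs arise by chance. Simulated unchanged groups sharing those libraries gave 91.1 such genes on average over 100 draws, and independent lists of the same sizes would give 4.48. The fold changes of the comparisons correlated across genes at r = -0.61, against -0.45 in simulation (95% of draws from -0.83 to 0.19), and genes are not independent replicates. Their covariance was -0.0767, against -0.0533 in simulation (from -0.173 to 0.0193). With the aged/doxo libraries split 2 and 2, so that none was shared, r ranged from -0.24 to 0.40 over 6 splits. Weighting libraries by quality gave 14 genes at the adjusted threshold.

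The third comparison asks how treated liver differed from young control liver. It shares the young control libraries with the first comparison, so a change found in both was not observed independently. Of 18 measured p53 target genes, 9 were higher in treated liver when adjusted over the list alone, none was lower and 9 did not pass. Phlda3 stood at 5.70 ± 2.37 against 0.56 ± 0.23 TPM (log2 fold change 2.03, SE 0.29) and also passed over all genes (limma adjusted p = 0.0418, n = 4). Cdkn1a stood at 25.3 ± 5.50 against 4.98 ± 3.05 TPM (log2 fold change 2.26, SE 0.37), Aen at 13.7 ± 1.99 against 5.69 ± 0.865 TPM (log2 fold change 1.14, SE 0.19) and the stress-response gene Trp53inp1 at 7.53 ± 1.65 against 2.53 ± 0.925 TPM (log2 fold change 1.29, SE 0.30). The median of the list was 0.53, against 0.23 for all genes, and its estimated-correlation p was 0.0135 (adjusted p = 0.236). Between 7 and 9 members passed without each library.

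Over all genes limma called 3 genes, 2 higher and 1 lower in treated liver, and 370 had an unadjusted p under 0.05. Besides Phlda3 they were Gm45941 (6.27 to 16.1 TPM in treated against 0.13 to 0.63 TPM in young control libraries, log2 fold change 3.19, SE 0.32, limma adjusted p = 0.00221, n = 4) and Gm47551 (log2 fold change -4.38, SE 0.55, limma adjusted p = 0.015), both chosen after their values were seen. Gm47551 stood at 68.1, 16.7, 12.4 and 27.5 TPM in young control libraries. Gm45941 passed under all 25 alternatives run for it, while Phlda3 passed under 7 of 24 and Gm47551 under 16 of 25. The Phlda3 call was kept without aged/doxo library 2 or treated library 4 and lost without any one of the others. The Gm47551 call was lost without young control library 4 or treated library 1, 2 or 3. Among genes not passing, Cplane1, Atp8b5 and Wdr27 had log2 fold changes of 1.55, 1.11 and 1.13, and Snhg9 one of -2.12.

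Of the 30 male-biased genes 8 fell, none rose and 22 did not pass when adjusted over the list alone. Mup1, Mup12, Mup16 and Mup17 had log2 fold changes of -1.04, -1.10, -1.04 and -1.50. Mup15, in no list, did not pass (log2 fold change -1.35). All Mup genes held 12.6% ± 2.39 of TPM in treated liver (SD, n = 4), against 19.5% in young control liver (exact permutation p = 0.0571) and 11.97% in aged/doxo liver (exact permutation p = 0.743). The list's estimated-correlation p was 0.00451 (adjusted p = 0.158), and no member passed without young control library 1 or 3 or treated library 2 or 3, with no filter or with the compared groups alone. There were 4 with a pseudocount of 0.1 or 0.01, with a mean TPM of at least 5, with the robust fit, or without young control library 2, aged/doxo library 4 or treated library 4, 5 without treated library 1 or with median-of-ratios scaling, and 2 without aged/doxo library 3. Of the NRF2 targets, Gsta1 and Gstm3 rose adjusted over the list alone, with log2 fold changes of 1.44 and 1.06, and 27 did not pass, including Aox1 (0.71) and Gstp1 (-0.62). The NRF2 list's estimated-correlation p was 0.216 (adjusted p = 0.8), and 9 members were higher without aged/doxo library 2, 1 without young control library 1 and 0 without treated library 1. There were 0 with the replicate number as a block, 1 under either rescaling or the reduced total, 6 with the compared groups alone and 12 with library weights.

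Endothelial markers had a median log2 fold change of 0.49 over 28 genes, with 0.77 for Ptprb, 0.80 for Ehd3, 0.56 for Esam and 0.58 for Bmp2, and none passed adjusted over the list alone (estimated-correlation p = 0.191, adjusted p = 0.8), while 9 passed without young control library 4. At the preset correlation 9 lists were higher and 8 lower, of 35, and 0 passed with an estimated correlation or fry, where 3 and 2 had an unadjusted p under 0.05. The median of 3 of these 17 lists, and the mean of 4, had the opposite sign to the test. There were 10 lists without young control library 1, 10 without treated library 2 and 11 without treated library 4. Of the panel, 0 genes passed, and Cdkn1a and the chromatin protein gene Hmgb2 (4.07 against 2.80 TPM) reached the smallest exact permutation p of 0.0286, or 0.343 after adjustment. As in the first comparison, so few genes at that p could not pass over the panel.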

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

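The divisions of the libraries into other groups were prescribed, and the tests of gene length across lists and of male-biased genes other than Mup genes were chosen before their results were seen. All other tests here were chosen after the result was seen. A library was singled out where its gap to the nearest library of its group exceeded Dixon's critical share of the group's range, which chance alone does in about 1 in 20 groups. It did so in 25 of 345 groups (7.25%), of which 12 lay in aged/doxo library 2 and 1 in young control library 1.

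In aged/doxo library 2, mitochondrial transcripts held 27.6% of TPM against 9.82% to 11.5% in the others of its group, and the 50 most abundant genes held 68.4% against 52.1% to 54.4%. In the same library Gstm1 stood at 4305 TPM (others 1671 to 1899), Mup16 at 4155 (2484 to 2687), Pck1 at 62.8 (173 to 188), Phlda3 at 2.84 (5.10 to 5.56), Snhg9 at 13.5 (4.51 to 5.52) and Hmgb1 at 23.1 (48.6 to 51.7). Its mean log2(TPM + 1) was 10.46 over hepatocyte secreted protein genes (others 11.11 to 11.21), 5.38 over pericentral genes (6.40 to 6.60), 4.93 over selenoprotein genes (5.91 to 6.03) and 4.02 over adipocyte genes (4.55 to 4.57).

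In aged/doxo library 4, Col1a1 stood at 2.32 TPM (others 1.13 to 1.30), Ehd3 at 11.8 (7.88 to 8.43) and Gsta1 at 8.62 (11.7 to 12.2), and cholangiocyte markers averaged 2.30 on the log2(TPM + 1) scale (1.98 to 2.03). In young control libraries, Gpx6 stood at 1.10 TPM in library 4 (others 0.64 to 0.70), and cell cycle genes averaged 1.49 in library 1 (1.82 to 1.87). In treated library 4, Aox1 stood at 30.1 TPM (others 32.8 to 33.3), Lmnb1 at 2.88 (1.66 to 1.85) and Gm47551 at 1.47 (0 in the others). Treated library 1 held Gstm3 at 109 TPM (others 75.8 to 80.1) and Nexn at 3.77 (0.14 to 0.19), and treated library 3 held Snhg9 at 5.22 (0 in the others) and Tagln at 2.96 (3.82 to 3.97).

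In other divisions of the same 8 libraries into 4 and 4, only the genes called between treated and young control liver outnumbered those of every other division. The real division gave 3 genes and the highest other 1 (1 of 35 divisions gave as many). That share is the smallest possible here, it is 1 of 6 such tests, and the count was 1 without treated library 2, with the replicate number as a block, with no filter or with the compared groups alone. Chance is therefore not excluded there. Nor could it be excluded for the genes called between aged/doxo and young control liver (1 gene, highest other 3315, 7 of 35) or between treated and aged/doxo liver (1 gene, highest other 1, 5 of 35). The division giving 3315 genes set young control libraries 1 and 3 and aged/doxo libraries 2 and 4 against the rest. These libraries lay lowest of the 8 on the first principal component (-95.6 to 0.04, against 9.02 to 28.2). They also had the steepest slopes on gene length (-0.473 to -0.355, against -0.348 to -0.252), so this division follows the main axis of variation described above. For gene lists chance could not be excluded in any comparison: 15 lists against a highest other of 22 for aged/doxo and young control liver (13 of 35), 18 against 23 for treated and aged/doxo liver (5 of 35), and 17 against 21 for treated and young control liver (4 of 35).

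The lists called between treated and aged/doxo liver moved with gene length, with a Spearman rho of median log2 gene length and mean log2 fold change of 0.616 across the 35 lists and 0.264 across genes. Without aged/doxo library 2, the mean log2 fold changes of the 18 called lists relative to all genes kept a median of 0.779 of their size (quartiles 0.598 and 0.914). Over all 35 lists, the slope of these values on those of the main fit was 0.61. Part of their size thus rests on that library. It is argued against as the sole cause only under a bound set after the values were seen, and a stricter bound left this open. Of the 18 lists, 16 were called in the same direction without aged/doxo library 2, 8 without aged/doxo library 4 and 7 with the length slope as a covariate. The 18 kept a median of 0.81 of their size without aged/doxo library 4 (quartiles 0.48 and 1.01, 1 turned sign). With the covariate they kept 0.42 (quartiles 0.30 and 0.63, 2 turned sign). The preset correlation behind these calls gave 11.7 of 35 lists on average in simulated unchanged data for aged/doxo against young control liver. The covariate nearly followed the first principal component (Spearman rho = 0.972), so the fit with it cannot tell gene length from anything else on that axis. Slopes of treated and aged/doxo libraries gave an exact permutation p of 0.143 (0.429 adjusted over 9 tests). A difference in how TPM depends on gene length may underlie the list calls, and an effect of the compound stays open.

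Over the list alone, 4 of 18 p53 target genes passed as higher in aged/doxo and 9 in treated than in young control liver, while the whole list did not pass with an estimated correlation (adjusted p = 0.172 and 0.236). Both comparisons use the same young control libraries, so these counts are not independent of each other. In treated liver 9 members passed with the length slope as a covariate. The mean log2 fold change was 0.61 in place of 0.79, while the median of all genes was 0.04 in place of 0.23. The fall in the list mean thus went with a like fall in all genes. The kept calls argue against length dependence as the whole cause there. Slopes of treated and young control libraries overlapped, however (means -0.29 and -0.36, exact permutation p = 0.343), which limits this test. In aged/doxo liver 10 passed, but its slopes hardly differed from young control (-0.39 against -0.36, exact permutation p = 0.629). The covariate thus had little to remove from that comparison and cannot test it. A single library as the cause is argued against, since at least 3 and 7 passed without each library. For 7 of 8 marker lists of other cell types, medians lay below those of all measured p53 target genes (0.39 and 0.53) in at least 1 group. The gap exceeded the SD between the genes of the list, which argues against a like rise of these markers in both groups. That SD does not bound a shift in cell make-up, and some lists held only 6 measured genes. Neutrophil markers, with 4 measured, were not tested, so the part of cell make-up is not settled. Stellate cell genes, at 0.24 and 0.32, lay within their SD of the p53 target medians. The largest medians were 0.37 (erythroid) in aged/doxo and 0.49 (endothelial) in treated liver. Stellate cells, or a different type in each group, therefore cannot be told apart from a p53 response. Age and doxorubicin cannot be told apart either, because the labels of all 4 aged/doxo libraries name both.

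All Mup genes together held a lower share of TPM in aged/doxo than in young control liver (exact permutation p = 0.0286, 0.257 adjusted over 9 tests of library measures). Reads shared between copies would leave the total unmoved, but the shares did not overlap (at least 15.0% in young control, at most 13.9% in aged/doxo liver). Young control library 1 held the highest share (26.5%), so leaving it out could not make the groups overlap and cannot decide its part. Without that library the mean log2 fold change of Mup genes was -0.45 in place of -0.65, so part of the fall rests on it. On a total without the 50 most abundant and the mitochondrial genes, the mean log2 fold change of Mup genes went from -0.65 (SE 0.24, exact permutation p = 0.0286) to -0.63 (SE 0.36, p = 0.114), so the call ended because the spread grew while the fold hardly moved. Quantile normalization gave -0.55 (exact permutation p = 0.0286) and median-of-ratios scaling -0.56 (0.2), and it is this spread that leaves a few abundant genes open. The 20 male-biased genes other than Mup genes had a mean of -0.68 (exact permutation p = 0.114) and of -0.38 without aged/doxo library 2, so lower male-biased expression in general cannot be told apart, and whether age or doxo is behind it was not tested.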

How the results depend on the processing

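The fits without young control library 1 and aged/doxo library 2 together and with gene length as a covariate, and the permutation test of list means, were chosen after the data were seen. Of 85 fold changes of named genes, 84 kept their direction under every alternative run, and 52 of the 80 not called were called under none. The genes were mainly chosen for small p-values in these same libraries, so a kept direction is largely built in by that choice. The 1 that turned was Cdkn1a between treated and aged/doxo liver. Of the 85 fold changes 12, all between treated and aged/doxo liver, fell by over 2 times under at least 1 alternative without turning. Apart from the explanations weighed above for the list calls, the p53 target genes and the Mup genes, the cause of the changes was not tested.

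For aged/doxo against young control liver, 1 gene was called. The count was 2 with a pseudocount of 0.1 or 0.01, 0 with no filter, 3 with median-of-ratios scaling, 2 with quantile normalization, 3 on a total without the 50 top and mitochondrial genes, 74 with library weights, 0 with the compared groups alone and 2 with the length covariate. Without each library it was 0 to 2. For treated against aged/doxo liver, 1 gene was called. It was 0 with a pseudocount of 0.01, no filter, median-of-ratios scaling, quantile normalization, both doubted libraries left out or the length covariate, 77 with library weights and 2 with the compared groups alone. Without each library it was 0 to 1. For treated against young control liver, 3 genes were called. It was 1 with no filter or the compared groups alone, 5 on the reduced total and 29 with library weights. Without each library it was 1 to 5. Genes changed in opposite directions numbered 0, and 14 with library weights.

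With the replicate number as a block the counts were 0, 0 and 1. The numbers do not pair libraries: of 12 same-number pairs 2 correlated above 0.1, 2 were closest to their own number, and r ranged from -0.58 to 0.39.

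With an estimated correlation, fry or list means, 0 lists were called in each comparison. For treated against aged/doxo liver the length covariate gave 11 lists in place of 18, and the fits without each library gave 11 to 18. Ribosomal protein genes turned direction under that covariate (adjusted p = 0.0152). For treated against young control liver, 8 lists were called without both doubted libraries in place of 17, and 10 to 21 without each library.

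The difference in Cdkn1a between treated and aged/doxo liver, 0.19, was -0.17 with median-of-ratios scaling, -0.12 with quantile normalization, -0.00790 on the reduced total, -0.0277 with library weights, -0.0524 without both doubted libraries and -0.33 with the length covariate. Without each library it was -0.0524 (without aged/doxo library 2) to 0.36.

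Over the list alone, p53 target genes higher than in young control liver numbered 3 to 13 in aged/doxo liver in place of 4, and 6 to 9 in treated liver in place of 9, apart from the fit without a filter, which gave 7 and 13 of 29. Male-biased genes lower numbered 0 to 15 in place of 7, and 0 to 11 in place of 8. NRF2 targets higher numbered 1 to 11 and 0 to 12, in place of 2 each. For treated against aged/doxo liver, library weights gave 25 endothelial genes in place of 0, and median-of-ratios scaling gave 5 erythroid genes lower in place of 0.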

Other observations

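These genes were chosen after their values were seen, and no test was planned for them. The lectin gene Mbl2 stood at 529 ± 214 TPM in aged/doxo and 596 ± 91.6 TPM in treated liver, against 250 ± 38.3 TPM in young control liver (SD, n = 4), with 216 TPM in aged/doxo library 2. Eda2r, a p53-induced receptor gene below the filter, stood at 0.01 to 0.07 TPM in young control, 0.20 to 0.49 TPM in aged/doxo and 0.33 to 0.78 TPM in treated libraries. Mgp stood at 8.99 ± 4.37 TPM in aged/doxo liver, 3.08 ± 0.706 TPM in young control and 2.68 ± 1.35 TPM in treated liver.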
